A study of Mus musculus with 6 samples.

How the data were processed

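RNA was measured by sequencing in 6 libraries of mouse cells: 2 of embryonic fibroblasts (MEF), 2 of a myeloid-like cell complex (MCC) and 2 of induced macrophages (iMac). The deposited table holds raw counts of reads per gene for each library, which the authors made, per the submitters' processing notes, with STAR against the mm10 genome and with featureCounts. The notes give no versions. The gene annotation, the strand setting and the handling of reads that match several places are not given in the sources used here. Per the labels' protocols, total RNA was taken with Trizol and libraries were made with an mRNA kit.

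Counts were whole numbers and were used as deposited. The 30445 gene symbols were matched to GENCODE mouse release 21 on GRCm38, the same assembly as mm10, for coordinates and for exonic bases shared with other genes; 29529 matched, and 8 of these named more than 1 gene there. Library totals ranged from 34389817 to 39174367 counts. The lowest level that could be seen was set at 3 counts over a group. A fold against a group with no counts is given as a lower bound against that floor, a fold against a group with 1 to 3 counts as a ratio with its 95% counting interval, and no fold is given where both groups were at or under 3 counts. Levels are counts over the scaled library total in units of 1e6 (CPM) after scaling, as mean and SD over the 2 libraries of a group.

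Genes were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr, scaling by TMM, and the two-sided quasi-likelihood test (glmQLFit, glmQLFTest) on all 6 libraries with group as the only term, which leaves 3 residual degrees of freedom among libraries. The filter removed 11832 genes and left 18613. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05; the number of genes that also changed by a log2 fold change of at least 1 is given as well. Fold changes carry the standard error taken from the fold change and its F statistic, with a prior count of 0.125. The comparisons were MCC against MEF, iMac against MEF and iMac against MCC, and the first pair share the MEF libraries. Their overlap was set beside 20 simulations with no effect and the same shared libraries.

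The 38 gene lists cover macrophage and leukocyte identity, other blood and tissue cell types, macrophage functions, Myc and its targets, cell cycle, metabolism, matrix and Hox genes. Each list with at least 3 tested genes was compared with all other genes by camera in limma 3.58.1 with a preset correlation of 0.01, two-sided, adjusted over the lists. The same test with a correlation estimated per list, and fry, which tests whether a list's genes move one way on balance, were run beside it. Counts of list members are over all genes tested, and the count adjusted over the list alone is added where it differs. Members counted as rising or falling are those called at the threshold. A count of 0 does not mean that no member moved that way.

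The tests, lists, alternatives and the rule for naming genes were fixed before the data were examined. Named in every comparison were Myc, Spi1, Cebpa, Csf1r, Adgre1, Cd68, Itgam, Ptprc, Lyz2, Col1a1, Thy1 and Pdgfra. Added were the 10 largest rises and the 10 largest falls among changed genes with a mean of at least 20 CPM in the higher group and no overlap between the groups' libraries, without predicted genes, and up to 4 members of each list. These 4 were the changed members with the largest fold changes, filled up with the most highly expressed others. Members that moved against the rest of their list are named as well, and they were chosen after their values were seen. Not every gene that the naming rule picks is reported.

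Alternatives were other scaling (median-ratio size factors), DESeq2 1.42.0, limma-voom, no filter on low counts, a stricter filter of 5 CPM in 2 libraries, a fit of only the groups compared, a block for replicate number and leaving out each library in turn. A fit that leaves out a library has 1 library in that group, which is assumed to vary like the other groups. Further alternatives for members of lists and for library totals without scaling were added after the data were seen. The pipeline was tested on simulated data with 18058 genes past the filter: of genes changed 2-fold it called 0% for MCC against MEF, 0% for iMac against MEF and 2.06% for iMac against MCC, and of genes changed 4-fold it called 21.6%, 22.6% and 40%. Lists were tested there for iMac against MEF only. Camera with the preset correlation called 19 of 20 lists in which 5 genes of 15 were raised and 0 of 40 random lists. With an estimated correlation it called 0 of both kinds. Genes were drawn independently, so this cannot show how the preset correlation does where the genes of a list vary together. In the real counts for iMac against MEF the estimated correlation ran from -0.242 (granulocyte genes) to 0.911 (cholesterol synthesis genes). Figures and annotation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.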

Results

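Messenger RNA was sequenced from mouse embryonic fibroblasts (MEF), from cells labelled as a myeloid-like cell complex (MCC) and from induced macrophages (iMac), with 2 libraries in each group. The title of the series names c-Myc, the transcription factor encoded by Myc, as the factor used to turn fibroblasts into macrophages. How the MCC and iMac were made, and how the one relates to the other, is not given in the sources used here. The deposited counts summed to 39174367 and 36276168 in MEF, 36847857 and 35638956 in MCC, and 35740990 and 34389817 in iMac. Of 30445 genes in the table, 18613 had enough counts to be tested. The p-values given here cover no more than these libraries, since nothing in the labels says that the libraries came from separate cultures. Those of single genes measure only the spread between the libraries. Those of camera with the preset correlation, and the permutation p over Hox genes, take genes as the units and do not measure that spread. The counting intervals and floors cover counting error only.

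How far libraries of a group lay apart depended on the measure. The first principal component held 89.7% of the variance and placed MEF at -250.3 and -249.5, MCC library 1 at 38.9, MCC library 2 at 132.5, and iMac at 164.7 and 163.7. Between the libraries of a group, 2290 genes differed by more than 2-fold in MEF, 2948 in MCC and 1321 in iMac. The chi-square per degree of freedom, which weights abundant genes, was 159 between the MEF libraries, 52.3 between the MCC libraries and 10.1 between the iMac libraries. In MCC library 1 the collagen and matrix genes were at a median log2 difference of 3.60 above MCC library 2, the fibroblast and mesenchymal genes at 2.63 and the Hox genes at 2.67. The interferon response genes differed the other way, with a median of -1.26. In MEF library 1 the collagen and matrix genes were at a median of 1.05 above MEF library 2, and the cell cycle genes at -0.87.

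**Figure D1:**
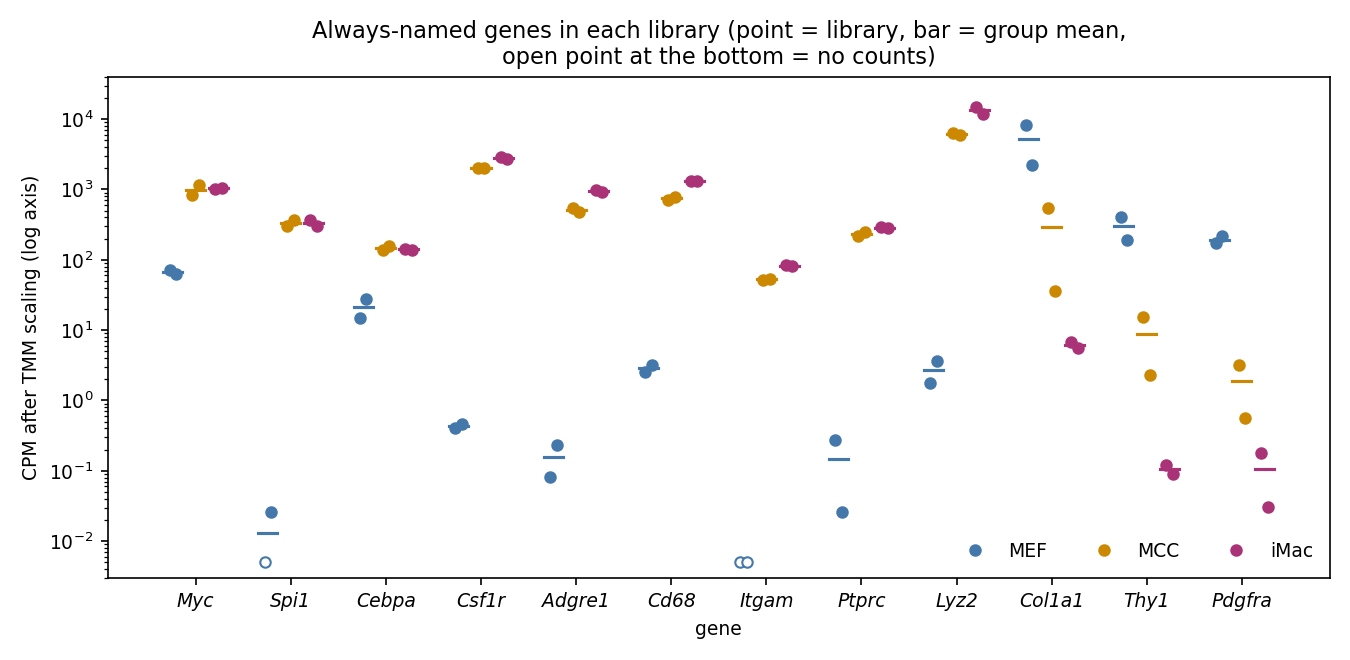
Levels of the 12 genes named in every comparison, in CPM on a log axis, with 1 point per library and the mean of each group. Myc sits at means of 66.9, 993 and 1041 CPM in MEF, MCC and iMac, and Csf1r at 0.435, 2019 and 2810 CPM.

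The first comparison asks how the MCC differed from the fibroblasts. All 20 macrophage identity genes and all 19 tested pan-leukocyte genes rose in MCC, with median log2 fold changes of 11.18 and 10.28, or 10.77 and 10.07 with genes at 0 in MEF set to their bound. Myc rose from 66.9 ± 5.36 CPM in MEF to 993 ± 241 CPM in MCC (SD, n = 2), a log2 fold change of 3.89 ± 0.21 (SE; adjusted p = 0.00043, edgeR quasi-likelihood test, Benjamini-Hochberg). Pdgfra, a growth factor receptor of mesenchymal cells, fell from 195 ± 30.1 to 1.87 ± 1.85 CPM, and Thy1, a surface protein of fibroblasts, from 301 ± 152 to 8.73 ± 9.09 CPM. In all, 9864 of 18613 genes changed, 4358 higher and 5506 lower in MCC, and 6753 of them changed at least 2-fold. Which direction held more genes depended on the libraries and the filter, with 4178 higher and 3514 lower without MEF library 2, and 3871 higher and 3656 lower among genes at 5 CPM or more in 2 libraries. Changes of at least 32-fold comprised 584 rises and 1317 falls.

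Genes of macrophages and of blood cells in general rose, most of them from low levels in MEF. Csf1r, the receptor for macrophage colony-stimulating factor, went from 0.435 ± 0.0404 to 2019 ± 19.9 CPM, a log2 fold change of 12.17 ± 0.19 (adjusted p = 4.68e-05). Adgre1, an adhesion receptor of mature macrophages, rose by 11.65 ± 0.41 on the log2 scale, Cd68, a glycoprotein of macrophage lysosomes, by 8.04 ± 0.18, and Lyz2, which encodes lysozyme, by 11.16 ± 0.53 to 6149 ± 199 CPM. Ptprc, a phosphatase found on nearly all leukocytes, rose by 10.61 ± 0.64. Itgam, an integrin of myeloid cells, had no counts in MEF and was at least 1325-fold higher in MCC, at 52.5 ± 2.35 CPM. Another annotated gene shares 68.7% of the exonic bases of Itgam, so its level is uncertain. Trem2, a lipid-sensing receptor of macrophages, was 7181-fold higher with a counting interval of 2457 to 34824. The macrophage identity list stood above other genes with camera adjusted p = 9.81e-67, and adjusted p = 0.0322 with an estimated correlation. The pan-leukocyte list gave 6.2e-71, and adjusted p = 0.0364 with an estimated correlation.

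Transcription factors of the myeloid line rose with these genes. Of 18 tested, 15 rose and 2 fell (camera adjusted p = 9.69e-17, and adjusted p = 0.061 with an estimated correlation). Spi1, which encodes PU.1, the main regulator of myeloid development, was at 0.0129 ± 0.0182 CPM in MEF and 338 ± 47.1 CPM in MCC, a ratio of 25570 with a counting interval of 4589 to 1.01e+06. Cebpa, a partner factor in myeloid development, rose by 2.79 ± 0.31 on the log2 scale from 21.4 ± 8.94 CPM. Irf8, a factor of monocytes and macrophages, rose by 9.69 ± 0.22, and Ikzf1, a factor of blood cells, by 10.65 ± 0.37. The 2 that fell were Klf4, at a log2 fold change of -3.41 ± 0.19, and Bach2, at -2.01 ± 0.24.

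Genes of macrophage functions rose as groups. Of 18 phagocytic receptors 15 rose, among them Fcgr3, an antibody receptor, by 11.92 ± 0.18, and Msr1, a scavenger receptor, by 12.37 ± 0.31 on the log2 scale. The 3 that fell, Axl (-1.97 ± 0.33), Megf10 (-5.04 ± 1.31) and Olr1 (-5.51 ± 0.43), are receptors also found outside the blood. Megf10 lost its call without MEF library 1 (adjusted p = 0.0672), MEF library 2 (0.102), iMac library 1 (0.0613) and iMac library 2 (0.0613). The phagocytic list gave camera adjusted p = 1.83e-25, and adjusted p = 0.0402 with an estimated correlation. Of 20 lysosomal genes 14 rose, or 15 adjusted over the list alone, including the proteases Ctss (13.13 ± 0.47) and Ctsb, which went from 819.5 ± 17.6 to 6444 ± 76.2 CPM. Camera gave adjusted p = 7.09e-10 for this list, and adjusted p = 0.272 with an estimated correlation. Of 18 pattern recognition genes 16 rose, or 18 adjusted over the list alone, among them the nucleic acid sensors Tlr13 (11.43 ± 0.46) and Tlr8 (11.18 ± 0.58), with adjusted p = 7.48e-27, and adjusted p = 0.0322 with an estimated correlation. All 8 tested genes of alternative activation rose, such as the mannose receptor Mrc1 (11.33 ± 0.42, to 2105 ± 157 CPM) and the lectin Clec10a (11.64 ± 0.63), with adjusted p = 1.02e-11, and adjusted p = 0.0923 with an estimated correlation.

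Complement, antigen presentation and cytokine genes were more mixed. Of 13 complement genes 9 rose, with C1qb at 12.69 ± 0.61 and C1qa at 12.44 ± 0.60, both parts of the starter complex C1q (adjusted p = 4.43e-17, and adjusted p = 0.118 with an estimated correlation). The 2 that fell were C1s1 (-3.82 ± 0.87) and Serping1 (-4.87 ± 1.27). Both lost their calls without MEF library 1, at log2 fold changes of -3.86 and -4.09, and without MEF library 2, at -3.67 and -5.27. Serping1 also lost its call without iMac library 1 or iMac library 2, at -4.85 in each fit. Of 14 antigen presentation genes 6 rose and 2 fell (adjusted p = 0.06, and adjusted p = 0.285 with an estimated correlation). Cd86, a costimulatory molecule, was at least 912-fold higher, and Cd74, the invariant chain, rose by 6.43 ± 0.49 to 20.9 ± 3.24 CPM. H2-Eb1, a class II chain, fell by 2.55 on the log2 scale to 0.119 ± 0.021 CPM, and Cd80, a costimulatory molecule, by 2.27. Of 13 inflammatory cytokine genes 5 rose, including the chemokine Ccl3 (10.22 ± 1.01) and Tnf (6.38 ± 0.90). Their camera adjusted p was 0.0347, and adjusted p = 0.523 with an estimated correlation. It was 0.0642 without MEF library 1, where 1 gene fell, 0.0686 without MEF library 2, and 0.168 without MCC library 1, where 3 fell. Of 16 interferon response genes 7 rose, or 6 adjusted over the list alone, such as the antiviral enzymes Oas2 (6.49 ± 0.63) and Oas1a (5.18 ± 0.42), with adjusted p = 0.0374, and adjusted p = 0.699 with an estimated correlation. Without MEF library 1 this was 3 genes and 0.124, without MEF library 2 it was 4 genes and 0.0792, and without MCC library 2 the adjusted p was 0.0802 and 1 gene fell.

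Genes of ribosome production rose with Myc, while its relatives Mycn and Mycl fell. Mycn had no counts in MCC and was at least 89.1-fold lower than in MEF, and Mycl fell by 5.15 on the log2 scale. Mnt, which binds the same partner as Myc, rose by 0.86 ± 0.11. Over the 9 genes of the Myc family and partners, 3 rose and 2 fell; the median log2 fold change was 0.21, the mean -1.03 and camera's direction up (adjusted p = 0.76). Of 20 Myc target and ribosome biogenesis genes 14 rose and 0 fell, with a median of 0.89 (adjusted p = 0.00109, and adjusted p = 0.418 with an estimated correlation). Polr1b, a subunit of RNA polymerase I, rose by 1.53 ± 0.15, and Nop56, a nucleolar protein, by 1.33 ± 0.11. The table gives 1 count per library for Myc and does not say whether reads from an introduced Myc sequence are in it.

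Cell cycle genes tended upward and p53 and senescence genes fell. Of 20 cell cycle genes 8 rose, or 7 adjusted over the list alone, with a median of 0.73 (adjusted p = 0.0303, and adjusted p = 0.699 with an estimated correlation). Mcm6, a part of the replication helicase, rose by 1.49 ± 0.22 and Pcna, the replication clamp, by 1.53 ± 0.30. The median was 0.38 without MEF library 1 and 1.28 without MEF library 2. The number that rose was 17 without MEF library 2 and 4 without each of MCC library 1, iMac library 1 and iMac library 2, and 1 gene fell without MEF library 1. Of 12 p53 and senescence genes 10 fell, or 12 adjusted over the list alone, with a median of -1.74 (adjusted p = 0.000278, and adjusted p = 0.299 with an estimated correlation). Among them were the cell cycle inhibitors Cdkn2b, which went from 136 ± 9.44 to 3.16 ± 2.88 CPM, and Cdkn2a (-4.10 ± 0.67), and the p53 target Ccng1 (-2.53 ± 0.20).

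Fibroblast, matrix and Hox genes fell, to levels that differed between the MCC libraries. Of 20 fibroblast and mesenchymal genes 17 fell, or 19 adjusted over the list alone, with a median of -4.85, or -4.71 with zeros at their bound (adjusted p = 0.000265, and adjusted p = 0.429 with an estimated correlation). Without MEF library 1 this was 10, and without MEF library 2 also 10. Of 20 collagen and matrix genes 16 fell, or 20 adjusted over the list alone, with a median of -4.96 (adjusted p = 0.000633, and adjusted p = 0.549 with an estimated correlation). This was 5 without MEF library 1 and 6 without each of MEF library 2, iMac library 1 and iMac library 2. Without MCC library 1 the median was -7.34 for the fibroblast and mesenchymal genes and -7.74 for the collagen and matrix genes, and without MCC library 2 it was -3.88 and -3.93. Col3a1, a fibrillar collagen, went from 3140 ± 892 to 41.4 ± 48.0 CPM, and Col6a3, a chain of type VI collagen, fell by 5.90 on the log2 scale. Col1a1, the main fibrillar collagen chain of fibroblasts, was at 5240 ± 4224 CPM in MEF and 290 ± 359 CPM in MCC. Its log2 fold change of -4.18 ± 1.40 did not pass (edgeR adjusted p = 0.055), and was -7.18 without MCC library 1 and -3.15 without MCC library 2. With each of a replicate block, DESeq2 and limma-voom, all 20 collagen and matrix genes fell, Col1a1 among them. Of 36 Hox genes, which mark position along the body, 26 fell, or 29 adjusted over the list alone, with a median of -4.60, or -4.56 with zeros at their bound (adjusted p = 9.58e-07, and adjusted p = 0.419 with an estimated correlation). This was 11 without MEF library 1, 8 without MEF library 2 and 16 without each of iMac library 1 and iMac library 2, and the median was -8.77 without MCC library 1 and -3.59 without MCC library 2. Hoxa13, a gene of distal limbs, had no counts in MCC and was at least 82.4-fold lower.

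Genes of 3 metabolic pathways were tested. Of 14 cholesterol synthesis genes 9 fell and 0 rose, with a median of -1.11, or -0.67 without MEF library 2 (adjusted p = 0.0162, and adjusted p = 0.668 with an estimated correlation). Fdft1, which makes squalene, fell by 1.83 and Cyp51, a sterol demethylase, by 1.52 on the log2 scale. Of 15 oxidative phosphorylation genes 10 rose, such as Cox5a (0.92 ± 0.11), a subunit of the last respiratory complex. Their camera adjusted p was 0.0933, and adjusted p = 0.648 with an estimated correlation. It passed when any 1 library was left out, at 0.00313 without MEF library 1, 0.00494 without MEF library 2, 0.00609 without MCC library 1, 0.00485 without MCC library 2, 0.023 without iMac library 1 and 0.0229 without iMac library 2. Of 14 glycolysis genes 3 rose, including Hk2, and 2 fell, the glucose transporter Slc2a1 (-1.54 ± 0.27; adjusted p = 0.0597 without MEF library 2) and the hexokinase Hk1 (-1.16 ± 0.09). The glycolysis adjusted p was 0.662, and without MEF library 1 it was 0.0101 with 9 genes up.

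The largest single changes included surface receptors of myeloid cells and genes of the starting culture. Ms4a4a, a membrane protein of macrophages, had no counts in MEF and was at least 2511-fold higher in MCC. Il7r, the receptor for interleukin 7, was at least 1304-fold higher. Agtr2, an angiotensin receptor, had no counts in MCC and was at least 3611-fold lower. Ntrk2, a neurotrophin receptor, was 2145-fold lower with a counting interval of 593 to 17715.

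**Figure D2:**
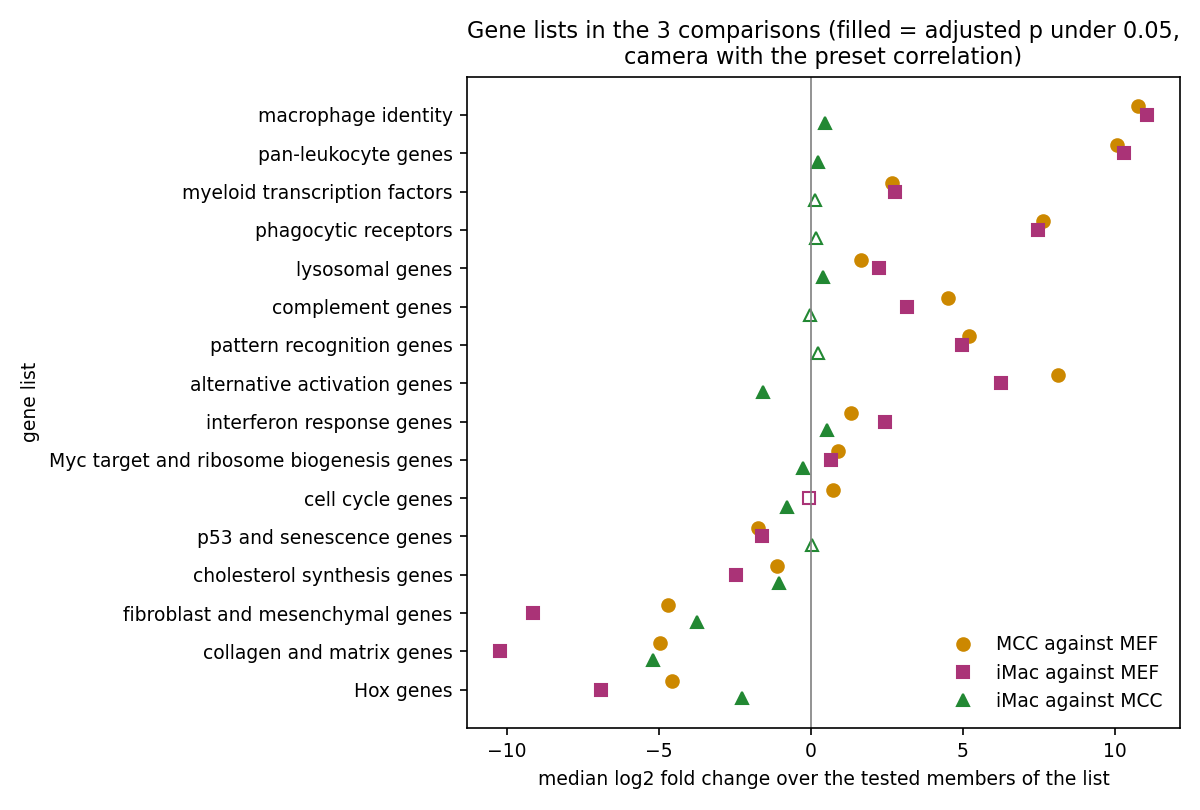
Median log2 fold change of the tested members of a selection of the 38 gene lists, by comparison. Genes at 0 in a group are set to their bound. Against MEF the macrophage identity genes have medians of 10.77 in MCC and 11.07 in iMac. The collagen and matrix genes have medians of -4.96 and -10.23.

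The second comparison asks how the induced macrophages differed from the fibroblasts. Again all 20 macrophage identity genes and all 19 tested pan-leukocyte genes rose, with median log2 fold changes of 11.12 and 10.41, or 11.07 and 10.29 with zeros at their bound. Myc was at 1041 ± 26.9 CPM, a log2 fold change of 3.96 ± 0.21 over MEF (SE; adjusted p = 0.000332, edgeR quasi-likelihood test, Benjamini-Hochberg). All 20 collagen and matrix genes fell with all 6 libraries, 9 without iMac library 1 and 8 without iMac library 2. Pdgfra fell to 0.105 ± 0.105 CPM and Thy1 to 0.105 ± 0.0205 CPM. In all, 10717 of 18613 genes changed, 4678 higher and 6039 lower, and 7588 changed at least 2-fold. Among genes at 5 CPM or more in 2 libraries it was 4007 higher and 3972 lower. Changes of at least 32-fold comprised 622 rises and 2556 falls. The number of changed genes was 5173 without iMac library 1 (2492 higher, 2681 lower) and 5197 without iMac library 2 (2519 higher, 2678 lower).

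Macrophage genes reached high levels in iMac. Csf1r was at 2810 ± 159 CPM, a log2 fold change of 12.64 ± 0.20, Adgre1 at 939 ± 41.7 CPM (12.51 ± 0.42) and Cd68 at 1329.5 ± 0.522 CPM (8.86 ± 0.19). Lyz2 reached 13397 ± 2378 CPM (12.28 ± 0.55), and Ptprc rose by 10.90 ± 0.64. Itgam was at least 2095-fold higher, at 83.0 ± 2.85 CPM. Tyrobp, a signalling adaptor of myeloid receptors, rose by 12.53 ± 0.31. Camera gave adjusted p = 3.41e-20 for the macrophage identity list and 3.41e-20 for the pan-leukocyte list. Each had adjusted p = 0.17 with an estimated correlation. Of 18 myeloid transcription factors 14 rose and 2 fell (adjusted p = 1.13e-06, and adjusted p = 0.256 with an estimated correlation). Spi1 was at 337.6 ± 43.0 CPM, 25583-fold above MEF with a counting interval of 4591 to 1.01e+06, Cebpa rose by 2.72 ± 0.31 and Irf8 by 10.44 ± 0.22. Klf4 (-4.09 ± 0.20) and Bach2 (-3.53 ± 0.26) fell.

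Genes for uptake, digestion and sensing rose. Of 18 phagocytic receptors 15 rose, such as Fcgr3 (12.84 ± 0.18) and the glucan receptor Clec7a (12.63 ± 0.63, with a counting interval of the ratio from 1439 to 3.17e+05), while Axl (-3.74 ± 0.36), Megf10 (-10.92 ± 1.95) and Olr1 (-5.32 ± 0.43) fell. Megf10 lost its call without iMac library 1 (adjusted p = 0.0645) and iMac library 2 (0.0588). The list gave adjusted p = 3.2e-08, and adjusted p = 0.256 with an estimated correlation. Of 20 lysosomal genes 17 rose, with Ctss at 13.03 ± 0.47 and Ctsb at 3.86 ± 0.16 (adjusted p = 2.7e-09, and adjusted p = 0.375 with an estimated correlation). Of 18 pattern recognition genes 16 rose, including Tlr7, a sensor of RNA, by 10.16 ± 0.40 (adjusted p = 1.58e-12, and adjusted p = 0.17 with an estimated correlation). Of 13 complement genes 10 rose, with C1qb at 12.80 ± 0.61 (adjusted p = 1.32e-05, and adjusted p = 0.375 with an estimated correlation). The 2 that fell were C1s1 (-6.23 ± 1.01) and Serping1 (-9.66 ± 1.73). Both lost their calls without iMac library 1, at log2 fold changes of -6.21 and -10.2, and without iMac library 2, at -6.22 and -9.26. All 8 alternative activation genes rose, with Mrc1 at 10.70 ± 0.41 and Clec10a at 13.06 ± 0.64 (adjusted p = 7.97e-06, and adjusted p = 0.256 with an estimated correlation).

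Interferon response genes rose and cytokine genes split. Of 16 interferon response genes 10 rose and 0 fell, with a median of 2.44 (adjusted p = 0.00154, and adjusted p = 0.533 with an estimated correlation). Oas2 rose by 7.03 ± 0.65 and Rsad2, an antiviral enzyme, by 5.14 ± 0.69. The count was 5 without MEF library 1, 5 without MEF library 2, 5 without iMac library 1 and 6 without iMac library 2. Of 13 inflammatory cytokine genes 6 rose, including Ccl3 (11.07 ± 1.02) and Tnf (6.59 ± 0.90). The 4 that fell were the chemokines Ccl2 (-4.16 ± 0.64), Ccl7 (-4.46 ± 0.72) and Cxcl1 (-2.42 ± 0.71), and Ptgs2 (-6.32 ± 1.58), an enzyme of prostaglandin synthesis (adjusted p = 0.169). This was 2 without MEF library 2, 2 without iMac library 1 and 1 without iMac library 2, and Ptgs2 had an adjusted p of 0.0639 without MEF library 1. Of 14 antigen presentation genes 6 rose and 2 fell, Cd80 (-2.61 ± 0.17) and H2-Eb1 (-1.75 ± 0.41), with adjusted p = 0.0961. Only 1 fell without each of MEF library 1, MEF library 2, iMac library 1 and iMac library 2, and the adjusted p without iMac library 2 was 0.0249. Cd86 was at least 1614-fold higher and Cd74 was at 18.2 ± 3.59 CPM.

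Myc target genes rose, and most cell cycle genes did not pass. Of 20 Myc target and ribosome biogenesis genes 11 rose, with a median of 0.66, and Nme1 (-0.89 ± 0.11), a nucleotide kinase, fell (adjusted p = 0.00748, and adjusted p = 0.413 with an estimated correlation). Polr1b rose by 1.39 ± 0.15 and Pes1, a factor of ribosome assembly, by 1.19 ± 0.09. Of 9 Myc family and partner genes 5 rose, or 3 without iMac library 1, and 2 fell; their median was 0.56, their mean -0.76 and camera's direction up (adjusted p = 0.234). Of 20 cell cycle genes 2 rose, or 1 adjusted over the list alone, and 2 fell, Rrm2 (-1.25 ± 0.23) and Ccne1 (-1.17 ± 0.20). Their median was -0.06 with camera's direction up (adjusted p = 0.753). Without MEF library 1, 9 cell cycle genes fell; without MEF library 2, 10 rose and the adjusted p was 0.012; without iMac library 1 or iMac library 2, 0 rose and 0 fell. Of 12 p53 and senescence genes 10 fell, or 11 adjusted over the list alone, with Cdkn2b at -7.09 ± 0.83 and Ccng1 at -2.74 ± 0.20 (adjusted p = 0.000535, and adjusted p = 0.375 with an estimated correlation).

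Mesenchymal genes fell to low levels in iMac. The 20 collagen and matrix genes had a median of -10.23 (adjusted p = 2.32e-06, and adjusted p = 0.405 with an estimated correlation). Col3a1 was at 0.479 ± 0.251 CPM, a log2 fold change of -12.67 ± 1.65, and Fn1, which encodes fibronectin, was at 48.8 ± 5.62 CPM (-7.82 ± 0.82). Col1a1 fell to 6.24 ± 0.891 CPM (-9.71 ± 1.80, adjusted p = 0.00888), a call lost without iMac library 1 (adjusted p = 0.0675) and without iMac library 2 (adjusted p = 0.0706). Of 20 fibroblast and mesenchymal genes 19 fell, or 9 without iMac library 1 and 9 without iMac library 2, with a median of -9.40, or -9.14 with zeros at their bound (adjusted p = 3.11e-06, and adjusted p = 0.405 with an estimated correlation). Pdgfra fell, at a log2 fold change of -10.81 ± 1.16, and so did Thy1, at -11.44 ± 1.44. Of 36 Hox genes 35 fell, with a median of -9.07, or -6.89 with zeros at their bound (adjusted p = 3.39e-08, and adjusted p = 0.405 with an estimated correlation). This was 22 without MEF library 1, 20 without MEF library 2, 11 without iMac library 1 and 11 without iMac library 2. Gpc3, a heparan sulfate proteoglycan, had no counts in iMac and was at least 4858-fold lower, and Slc1a3, a glutamate transporter, at least 4106-fold.

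**Figure D3:**
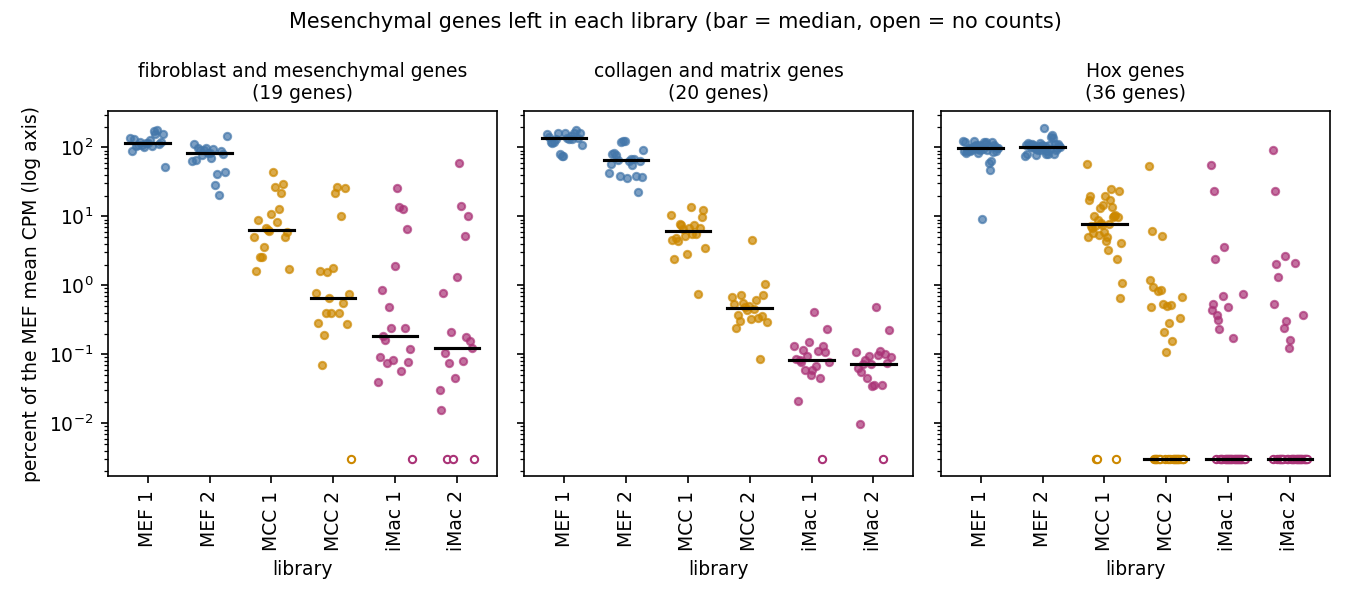
Median level of the fibroblast and mesenchymal, collagen and matrix, and Hox genes in each library, as a percent of their MEF mean. The collagen and matrix genes are at 6.05% in MCC library 1, 0.465% in MCC library 2, and 0.0838% and 0.0735% in the iMac libraries.

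Cholesterol synthesis genes fell in iMac. Of 14 tested, 13 fell, or 14 adjusted over the list alone, with a median of -2.45 (adjusted p = 5.96e-06, and adjusted p = 0.405 with an estimated correlation). Of 14 glycolysis genes 1 rose, Gpi1 (0.89 ± 0.10), and 3 fell, among them Slc2a1 (-2.18 ± 0.28) and Hk1 (-1.14 ± 0.09), with adjusted p = 0.753; without MEF library 1, 5 rose. Of 15 oxidative phosphorylation genes 8 rose, such as Atp5a1 (0.65 ± 0.11; adjusted p = 0.0682 without iMac library 2), and 2 fell, Ndufa4 (-0.29 ± 0.09) and Cycs (-0.37 ± 0.09), with adjusted p = 0.141. Without iMac library 1, 3 rose and 0 fell; without iMac library 2, 2 rose and 0 fell. Without MEF library 2, 0 fell, and without MCC library 1 or MCC library 2, 1 fell.

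Of the genes changed in both comparisons with MEF, 8787 changed the same way, 3793 higher and 4994 lower, and 12 changed in opposite directions. Csf1r, Spi1 and Myc are among those higher in both, and Pdgfra and Thy1 among those lower in both. Independent calls would give 1095.3 higher and 1786.4 lower in both. The MEF group holds 2 libraries and was not split, so part of the excess of the overlap over independent calls may come from the shared controls. The fold changes correlated over genes at 0.927, against a mean of 0.494 and a highest value of 0.522 in 20 simulations with no effect and the same shared MEF libraries. Their covariance was 10.124, against 0.161 in the simulations. The number of genes called the same way in both comparisons was 0 in every simulation. With no effect simulated, this does not show how much shared controls add where many genes change. The overlap was 4783 without iMac library 1 (2265 higher, 2518 lower) and 4747 without iMac library 2 (2248 higher, 2499 lower), and without MEF library 2 it held 3572 higher and 3248 lower.

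The third comparison asks what separated the iMac from the MCC, and the edgeR test called few genes. Rnf144b, a ubiquitin ligase, rose from 30.6 ± 1.92 to 169 ± 5.10 CPM, a log2 fold change of 2.46 ± 0.09 (SE; adjusted p = 0.0115, edgeR quasi-likelihood test, Benjamini-Hochberg). Tecpr1, a protein of autophagosome and lysosome fusion, rose from 58.6 ± 3.89 to 208 ± 0.336 CPM (1.83 ± 0.09, adjusted p = 0.0201). Id3, an inhibitor of helix-loop-helix factors, fell from 43.3 ± 1.56 to 1.04 ± 0.283 CPM (-5.38 ± 0.23, adjusted p = 0.0117). Npnt, which encodes a matrix protein and lies outside the naming rule, was chosen after its values were seen and fell by 5.22 on the log2 scale (adjusted p = 0.0115). These 4 genes were all that passed, 2 up and 2 down, and 3380 genes had an unadjusted p under 0.05. DESeq2 called 2560 genes, 1102 higher and 1458 lower, and limma-voom 146. An edgeR fit of only the 2 groups called 1364, 691 higher and 673 lower. With edgeR and all groups the count of 4 became 1202 without MCC library 2, with 66 higher and 1136 lower, 2 (Id3 and Npnt) without MCC library 1, and 0 without each of MEF library 1, MEF library 2, iMac library 1 and iMac library 2.

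The genes named in every comparison did not pass between iMac and MCC in the edgeR fit of all 6 libraries, and for most of them this depended on the fit. Myc was at 1041 ± 26.9 and 993 ± 241 CPM (log2 fold change 0.07 ± 0.19, adjusted p = 0.891), Spi1 at 337.6 ± 43.0 and 338 ± 47.1 CPM (-0.00 ± 0.22), and Cebpa differed by -0.08 ± 0.29 (adjusted p = 0.925). Csf1r differed by 0.48 ± 0.12 (adjusted p = 0.179), Adgre1 by 0.86 ± 0.25 (0.206), Cd68 by 0.82 ± 0.13 (0.111), Lyz2 by 1.12 ± 0.35 (0.222), Itgam by 0.66 ± 0.11 (0.134) and Ptprc by 0.29 ± 0.39 (0.733). Col1a1 differed by -5.54 ± 1.51 (0.195), Thy1 by -6.33 ± 1.34 (0.149) and Pdgfra by -4.11 ± 1.15 (0.201); without MCC library 2 these 3 passed, at 0.0161, 0.00761 and 0.01. In the edgeR fit of only the 2 groups Csf1r passed (adjusted p = 0.0315), as did Adgre1 (0.0162), Cd68 (0.0124), Itgam (0.0173), Lyz2 (0.02) and Thy1 (0.0427). DESeq2 called these and also Col1a1 (0.000232) and Pdgfra (0.0109), limma-voom called Adgre1 (0.0473) and Cd68 (0.0374), and Myc, Spi1, Cebpa and Ptprc passed in none of the fits run. Simulated 2-fold changes were recovered at 2.06% in this comparison and 4-fold changes at 40%.

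Over all genes, edgeR called 0 members of any of the 38 lists here. Of the list tests only camera with its preset correlation called lists, 18 of them; fry called 0, and for every list the adjusted p was between 0.533 and 0.994 with an estimated correlation. Collagen and matrix genes had a median of -5.23 with 19 of 20 lower adjusted over the list alone (camera adjusted p = 6.45e-11); DESeq2 called 20 lower. Without MCC library 1 the median was -2.67 with 0 called by edgeR, and without MCC library 2 it was -6.23 with 18 called. Fn1 was at 998 ± 708 CPM in MCC and 48.8 ± 5.62 CPM in iMac, and passed without MCC library 2 (adjusted p = 0.0084). Fibroblast and mesenchymal genes had a median of -4.06, or -3.76 with zeros at their bound, with 8 of 20 lower adjusted over the list alone (1.59e-06); DESeq2 called 13. Without MCC library 1 the median was -1.36 with 0 called, and without MCC library 2 it was -5.01 with 13 called. Vim, the intermediate filament vimentin, was at 1212 and 632 CPM (-0.94 ± 0.12, adjusted p = 0.0839, and 0.0276 without MCC library 2). Hox genes had a median of -4.03, or -2.27 with zeros at their bound, with 0 adjusted over the list alone (0.000563); this was 0.116 without MEF library 2 and 0.964, with a median of 0.00, without MCC library 1, and without MCC library 2 18 fell, with a median of -5.06.

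Cholesterol synthesis, cell cycle, Myc target and glycolysis genes passed camera with its preset correlation, on the lower side in iMac, and 0 of their members passed edgeR over all genes. With an estimated correlation the adjusted p was 0.533 for each of the first 3 lists and 0.693 for glycolysis, and with fry it was 0.165, 0.205, 0.165 and 0.253. Cholesterol synthesis genes had a median of -1.05 with 14 of 14 lower adjusted over the list alone (adjusted p = 1.62e-12), DESeq2 called 12, and edgeR without MCC library 2 called 5. Cell cycle genes had a median of -0.79 with 2 of 20 lower adjusted over the list alone (5.32e-08), and DESeq2 called 8. Mki67, a marker of dividing cells, was at 431 ± 34.4 and 255 ± 24.8 CPM (-0.76 ± 0.35), and Top2a, a topoisomerase of dividing cells, differed by -0.89 ± 0.28. Myc target genes had a median of -0.27, or -0.42 without MCC library 2, with 3 of 20 lower adjusted over the list alone (0.00156), and DESeq2 called 7. Without MCC library 2 edgeR called 2 Myc target genes and 1 cell cycle gene lower. Glycolysis genes had a median of -0.42 with 0 adjusted over the list alone (0.00629), and 1 fell without MCC library 2.

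**Figure D4:**
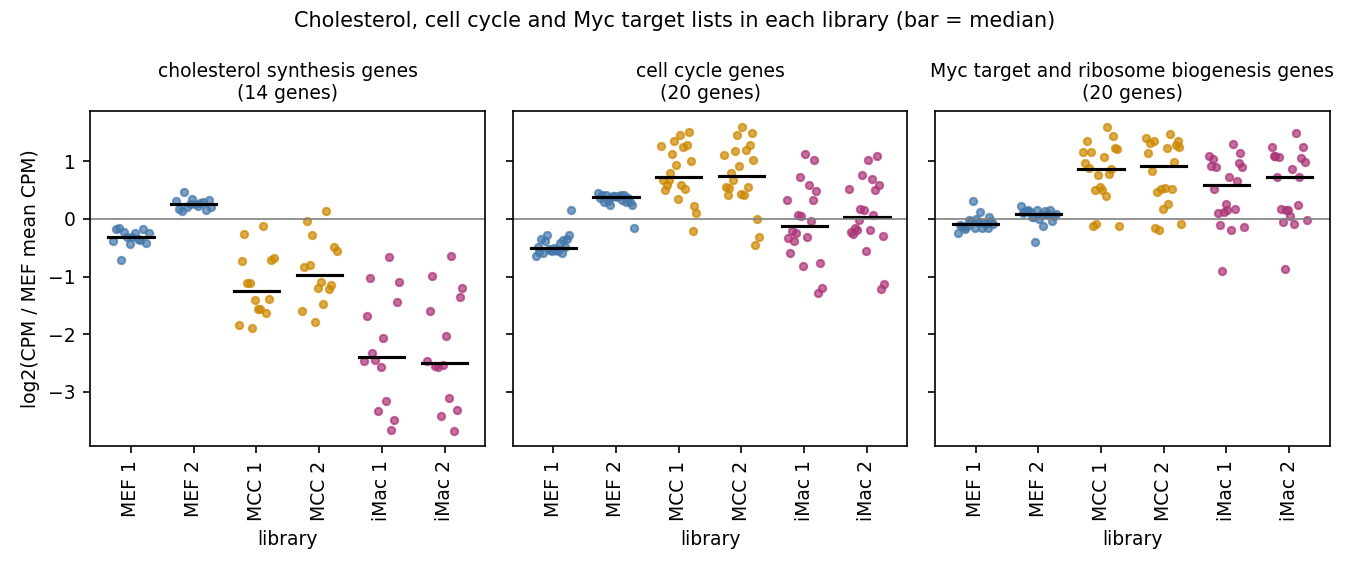
Median level of the cholesterol synthesis, cell cycle and Myc target genes in each library, as log2 of the level over the MEF mean. The cholesterol synthesis genes are at -1.26 and -0.97 in the MCC libraries and -2.39 and -2.49 in the iMac libraries, and the cell cycle genes at 0.73 and 0.73 in MCC and -0.13 and 0.02 in iMac.

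Macrophage identity, pan-leukocyte and lysosomal genes passed camera with its preset correlation, on the higher side in iMac, and 0 of their members passed edgeR over all genes. With an estimated correlation the adjusted p was 0.533 for each, and with fry it was 0.173, 0.165 and 0.205. Macrophage identity genes had a median of 0.47 with 11 of 20 higher and 2 lower adjusted over the list alone (adjusted p = 0.000563), and DESeq2 called 12 higher and 2 lower. Pan-leukocyte genes had a median of 0.25 with 0 adjusted over the list alone (0.00136), and DESeq2 called 6 higher. Lysosomal genes had a median of 0.40 with 4 higher and 1 lower adjusted over the list alone (7.76e-05), as with Ctsb at 6444 ± 76.2 and 11912 ± 815 CPM (0.89 ± 0.14, adjusted p = 0.111), and DESeq2 called 8 higher and 1 lower. Interferon response genes had a median of 0.51 with 0 adjusted over the list alone (0.000386), which was 0.352 without MCC library 1. Their median was 0.24 without MCC library 1, 1.40 without MCC library 2, 0.27 without iMac library 1 and 0.82 without iMac library 2. Alternative activation genes went the other way, with a median of -1.57 and 1 higher and 3 lower adjusted over the list alone (0.00324), which was 0.071 without MEF library 2, and the median was -0.76 without MCC library 1. Cd163, a haemoglobin scavenger receptor, was at 151 ± 19.9 CPM in MCC and 13.7 ± 9.37 CPM in iMac (-3.47 ± 0.60, adjusted p = 0.122), and Mrc1 differed by -0.63 ± 0.27.

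Of the remaining function lists, 1 passed camera with its preset correlation between iMac and MCC. Myc family genes had a median of 0.28, or 0.14 without MCC library 2 and 0.18 without iMac library 2, with 0 adjusted over the list alone (adjusted p = 0.0319), which was 0.0519 without MEF library 1, 0.051 without MEF library 2, 0.0803 without MCC library 2 and 0.0521 without iMac library 1. Phagocytic receptors had 6 higher and 3 lower adjusted over the list alone, with a median of 0.17, a mean of -0.22 and camera's direction up (0.189), and Fcgr3 differed by 0.92 ± 0.10 (adjusted p = 0.0756). Myeloid transcription factors had 2 higher and 4 lower adjusted over the list alone, with a median of 0.13, a mean of -0.12 and camera's direction up (0.806). Complement genes had 1 lower (0.895), inflammatory cytokine genes 2 lower (0.388), with Ccl2 at 98.8 ± 77.5 and 7.91 ± 0.882 CPM (adjusted p = 0.0017 without MCC library 2), and pattern recognition genes 0 (0.165) adjusted over the list alone. Antigen presentation genes had 0 adjusted over the list alone (0.228), with a median of 0.26, a mean of -0.00 and camera's direction up, and the adjusted p was 0.0374 without iMac library 2. The p53 and senescence genes had 0 adjusted over the list alone, with a median of 0.03, a mean of -0.17 and camera's direction up (0.634), which was 0.0325 without MCC library 1. Oxidative phosphorylation genes had 2 lower adjusted over the list alone (0.0921), which was 0.0352 without MEF library 1, 0.007 without MEF library 2 and 0.0142 without MCC library 1.

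The 12 genes named in every comparison lie, on GRCm38, at these places. Myc is on chromosome 15 from 61985391 to 61990374, Spi1 on chromosome 2 from 91082390 to 91115756, Cebpa on chromosome 7 from 35119293 to 35121928 and Csf1r on chromosome 18 from 61100598 to 61132149. Adgre1 is on chromosome 17 from 57358691 to 57483527, Cd68 on chromosome 11 from 69664213 to 69666153, Itgam on chromosome 7 from 128062640 to 128118491 and Ptprc on chromosome 1 from 138062861 to 138175708. Lyz2 is on chromosome 10 from 117277331 to 117282321, Col1a1 on chromosome 11 from 94936224 to 94953042, Thy1 on chromosome 9 from 44043384 to 44048579 and Pdgfra on chromosome 5 from 75152292 to 75198215. Of the genes that passed between iMac and MCC, Rnf144b is on chromosome 13 from 47122656 to 47247991, Tecpr1 on chromosome 5 from 144194442 to 144223615 and Id3 on chromosome 4 from 136143497 to 136145755. All are annotated as protein-coding genes, and counts are over their exons.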

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

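The alternatives for members of lists, for library totals without scaling and for genes beyond those named in every comparison were added after the data were seen. The counts of changed genes for MCC against MEF (9864) stayed within 1.5 times under every alternative run, from 6753 at 2-fold or more to 10664 with DESeq2, and from 7194 to 8672 when 1 library was left out. For iMac against MEF (10717) the range was 7588 to 11408, and 5173 to 10695 when 1 library was left out, the lowest without iMac library 1. For iMac against MCC (4) the count was 89 with no filter on low counts, 1364 with only the groups compared, 2560 with DESeq2, 146 with limma-voom and 0 to 1202 when 1 library was left out; the cause was not tested. With a replicate block, which pairs libraries by number, the counts were 9022, 9908 and 0; deviations of same-numbered libraries correlated across genes at 0.131 (MEF and MCC), -0.00688 (MEF and iMac) and 0.00226 (MCC and iMac), and nothing in the labels says that the numbers pair libraries. Lists shifted numbered 25, 22 and 18 for the 3 comparisons with the preset correlation, 4, 0 and 0 with an estimated correlation, and 30, 31 and 0 with fry, which asks another question; with 1 library left out they ranged over 22 to 27, 18 to 26 and 13 to 19. The overlap of both comparisons with MEF (8787) ranged from 6080 to 9332, and from 4747 to 8069 when 1 library was left out. Scaling moved the median log2 fold change of all genes, most for iMac against MCC (-0.16 with library totals, -0.02 with TMM); with median-ratio size factors it was -0.12 for both comparisons with MEF, against -0.05 and -0.06 with TMM. Fits that leave out a library have fewer samples, so a lower count of genes called there need not mean that fewer genes moved. In simulated counts of the same design, 21.6%, 22.6% and 40% of 4-fold changes were called in the 3 comparisons; few genes were changed there, and the fits of the real counts against MEF also called genes changed under 2-fold. Depth set the level that 3 counts in 1 library stand for, at 0.0766 to 0.0872 CPM. The floor used for folds was 3 counts over a group of 2 libraries, which lies lower.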

Other observations

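In this part, the tests of reads carried over from MEF and of Hox groups were chosen after the result was seen. Genes of other blood lineages were measured beside the macrophage genes. Listed members absent from the deposited table or with too few counts were not tested. Tested were 4 of 16 listed granulocyte, 4 of 16 lymphoid and 5 of 14 erythroid and megakaryocyte genes. It was 4 of 12 mast cell and basophil, 4 of 10 alveolar macrophage, 4 of 10 epithelial and 3 of 11 pluripotency genes. Results of these lists cover only members with counts in some libraries, and do not show that a lineage's genes rose as a whole. Csf3r, the receptor for granulocyte colony-stimulating factor, was at 68.5 ± 10.7 CPM in MCC and 110.2 CPM in iMac (means of 2 libraries, SD after the sign). Of 4 tested granulocyte genes 3 rose in MCC, or 4 adjusted over the list alone (camera adjusted p = 2.98e-07, and adjusted p = 0.0767 with an estimated correlation; 0.0558 without MEF library 1), and 3 rose in iMac (0.00444, and adjusted p = 0.281 with an estimated correlation; 0.157 without MEF library 1). Of 7 dendritic cell genes 4 rose in MCC (0.00235, and adjusted p = 0.287 with an estimated correlation; 0.121 with 1 lower without MEF library 1). In iMac 4 of them rose and 1 fell (0.0224, and adjusted p = 0.403 with an estimated correlation; 0.189 without MEF library 1), and the 1 that fell was 0 without MEF library 2, iMac library 1 or iMac library 2. Clec10a led the dendritic list in both. Of 4 lymphoid genes Il7r alone rose in MCC (0.0156, and adjusted p = 0.241 with an estimated correlation) and in iMac (0.0993). The lymphoid value for MCC was 0.133 without MEF library 1, 0.0599 with 2 genes up without MEF library 2, and 0.22 without MCC library 2, and 2 rose without MCC library 1; for iMac it was 0.0388 without iMac library 1, and 2 rose without MEF library 2, MCC library 1 or MCC library 2.

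Pf4, a chemokine of platelets and some macrophages, was at 181 ± 4.25 CPM in MCC and 276 ± 15.9 CPM in iMac. Of 5 erythroid and megakaryocyte genes 2 rose and 1 fell in MCC (camera adjusted p = 0.00394, and adjusted p = 0.194 with an estimated correlation). Leaving out any library ended that call, at 0.209 and 0.2 without MEF library 1 and 2, 0.105 and 0.135 without MCC library 1 and 2, and 0.0848 and 0.0851 without iMac library 1 and 2. In iMac 2 rose and 1 fell (0.117). Progenitor genes split: Tal1, a blood stem cell factor, was at least 1195.5-fold higher in MCC and at least 979.9-fold higher in iMac than in MEF, while Cd34 was at 107 ± 86.3 CPM in MEF and 0.424 ± 0.195 CPM in MCC. Of 12 tested, 4 rose and 6 fell in MCC, or 7 adjusted over the list alone (median -2.98, mean -0.92, camera's direction up, adjusted p = 0.62), and 4 rose and 7 fell in iMac (0.896; 4 fell without MEF library 2, iMac library 1 or iMac library 2). Of 4 mast cell and basophil genes 3 fell in MCC (0.0722; 0.0169 and 0.0396 without MEF library 1 and 2, 0.0129 and 0.0168 without MCC library 1 and 2, and 0.023 and 0.0229 without iMac library 1 and 2) and 4 in iMac (0.0406, and adjusted p = 0.405 with an estimated correlation; 0.0708 without MEF library 2). Of 9 osteoclast genes 5 rose in MCC, and 1 fell adjusted over the list alone (0.0275, and adjusted p = 0.26 with an estimated correlation). This was 0.0598 without MEF library 2 and 0.0671 without MCC library 1, and 1 fell without MCC library 1 or MCC library 2. In iMac 4 osteoclast genes rose and 1 fell, or 5 and 2 adjusted over the list alone (0.097; 0.0323 without iMac library 2), and the 1 that fell was 0 without MEF library 1, MEF library 2, iMac library 1 or iMac library 2.

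The MEF libraries held transcripts of neural and other non-fibroblast genes that were lower in the other groups. Gfap, a filament of glia, was at 23.3 ± 2.71 CPM in MEF and 0.265 ± 0.0799 CPM in MCC, and Map2, a neuronal cytoskeleton protein, at 119 ± 27.7 and 1.57 ± 1.16 CPM. Of 10 neural genes 9 fell in MCC (camera adjusted p = 0.000575, and adjusted p = 0.241 with an estimated correlation; 5 without MEF library 2) and 10 in iMac (0.000132, and adjusted p = 0.375 with an estimated correlation; 5 without iMac library 1 and 6 without iMac library 2). Emcn, a sialomucin of vessels, was at 27.3 ± 4.92 CPM in MEF and 0.133 ± 0.0772 CPM in MCC. Of 9 endothelial genes 3 rose and 4 fell in MCC (0.551), and 3 rose and 5 fell in iMac (0.558). Of 4 epithelial genes 2 fell in MCC (0.117; 1 without MEF library 1, 1 without MEF library 2, and 0.0468 without MCC library 1). In iMac 3 epithelial genes fell, or 4 adjusted over the list alone (0.0397, and adjusted p = 0.375 with an estimated correlation). That was 0.065 without MEF library 1 and 0.0708 without MEF library 2, and 1 fell without MEF library 2, iMac library 1 or iMac library 2.

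Muscle, fat and pluripotency genes were measured as well. Of 7 muscle genes 0 passed in MCC by edgeR (camera adjusted p = 0.76), with 1 lower without MEF library 2 and 1 without MCC library 1. In iMac 5 muscle genes fell, or 6 adjusted over the list alone (0.0628). This was 2 without MEF library 1, 3 (0.0331) without MEF library 2, 0 without iMac library 1 and 0 (0.0328) without iMac library 2, and the adjusted p was 0.043 without MCC library 1 and 0.0387 without MCC library 2. Lpl, a lipase also made by macrophages, was at 69.5 CPM in MEF, 1365 ± 140 CPM in MCC and 3024 ± 147 CPM in iMac. Of 8 adipocyte genes Lpl rose and 4 fell in MCC, or 5 adjusted over the list alone (0.76), and 2 rose and 5 fell in iMac (0.551). In MCC 2 fell without MCC library 1, 2 without MCC library 2 and 0 without MEF library 2, and 2 rose without MEF library 1 or MEF library 2. In iMac 2 fell without MEF library 2, and 1 rose and 1 fell without iMac library 1 or iMac library 2. Of 3 pluripotency genes 1 rose and 1 fell in MCC (0.928) and in iMac (0.899), and without iMac library 1 or iMac library 2 0 rose and 0 fell in either; in MCC the same held without MEF library 1 or MEF library 2, and 0 rose without MCC library 1. In iMac 2 fell without MCC library 1 or MCC library 2. Sox2 was at 45.2 ± 19.3 CPM in MEF.

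Markers of tissue macrophages were expressed in part. Fcrls, a receptor of microglia, was at 448 ± 224 CPM in MCC and 60.6 ± 10.5 CPM in iMac (log2 fold change of iMac over MCC -2.89 ± 0.42, edgeR adjusted p = 0.0956, and 0.00362 without MCC library 2). Of 10 microglia genes 7 rose and 1 fell in MCC (camera adjusted p = 2.94e-07, and adjusted p = 0.26 with an estimated correlation). The 1 that fell, Olfml3, lost its call without MEF library 1, MEF library 2 and MCC library 2, at log2 fold changes of -1.01, -1.15 and -0.72. In MCC Sall1 was at -9.7 without MCC library 1 and -3.48 without MCC library 2. In iMac 7 rose and 3 fell, Sall1, Tmem119 and Olfml3 (0.00674, and adjusted p = 0.405 with an estimated correlation; 0.0612 without MEF library 1, 0.0708 without MEF library 2, and 1 fell without iMac library 1 or iMac library 2). Sall1 lost its call without each of MEF library 1, MEF library 2, iMac library 1 and iMac library 2. Its log2 fold change in those fits was -14.8, -13.54, -14.33 and -14.34. Of 8 Kupffer cell genes 6 rose in MCC (0.00134, and adjusted p = 0.194 with an estimated correlation; 1 fell without MEF library 1), and 6 rose and 1 fell in iMac (0.00286, and adjusted p = 0.315 with an estimated correlation; 0 fell without MEF library 2, iMac library 1 or iMac library 2). Cd5l, a secreted scavenger protein, was at 22.7 ± 0.871 and 25.5 ± 8.25 CPM. Of 4 alveolar macrophage genes 2 rose in MCC (0.0597) and 3 in iMac (0.0843). In MCC 1 rose without MCC library 1, MCC library 2 (0.0431), iMac library 1 (0.0347) or iMac library 2 (0.0345), and in iMac 1 rose without iMac library 1 or iMac library 2 (0.0317). Of 7 peritoneal macrophage genes 2 rose and 4 fell in MCC (0.76; 1 rose without MEF library 1), and 1 rose and 5 fell in iMac (0.103; 3 fell without iMac library 2). Gata6, the main factor of peritoneal macrophages, was at 0.0795 ± 0.0389 CPM in MCC.

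Between iMac and MCC, edgeR called 0 members of these lists over all genes tested, where 3380 genes had an unadjusted p under 0.05 and DESeq2 called 2560. Lmo2, a factor of blood progenitors, was at 68.0 ± 4.41 CPM in MCC and 204.5 ± 22.3 CPM in iMac (1.59 ± 0.23), and progenitor genes had 2 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.817). Muscle genes had 3 lower (0.000245), neural genes 4 lower (0.000276), granulocyte genes 1 higher and 2 lower (0.573), microglia genes 1 higher and 3 lower (0.0377), peritoneal macrophage genes 3 lower (0.0176) and alveolar macrophage genes 1 lower (0.571) adjusted over the list alone. Erythroid and megakaryocyte genes had 2 higher, with a median of -0.11, a mean of 0.13 and camera's direction up (0.228). Epithelial genes had 0 (0.0378), as had mast cell and basophil (0.216), dendritic cell (0.228), lymphoid (0.571), osteoclast (0.688), endothelial (0.703), adipocyte (0.634), Kupffer cell (0.987) and pluripotency genes; the last had a median of -5.14, a mean of -3.07 and camera's direction up (0.99). Each of these had an adjusted p of at least 0.533 with an estimated correlation. The epithelial value was 0.0988 without MEF library 1, 0.164 without MEF library 2 and 0.0674 without MCC library 2. The microglia value was 0.318 without MEF library 1, 0.48 without MEF library 2, 0.122 without MCC library 1 and 0.232 without iMac library 1, and the peritoneal value 0.268 and 0.473 without MEF library 1 and 2. The mast cell value was 0.0161 without MCC library 2. In that fit 5 neural, 3 muscle, 3 microglia and 3 peritoneal macrophage genes fell, as did 1 gene each of the mast cell, osteoclast, epithelial, Kupffer cell and pluripotency lists, and 1 progenitor gene rose and 3 fell.

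All 6 libraries held both Xist, the transcript of the inactive X chromosome, and genes of the Y chromosome. Xist ranged from 196 CPM in iMac library 1 to 293 CPM in MEF library 2. Ddx3y, a helicase gene on the Y chromosome, was at 40.4 and 43.5 CPM in MEF, 48.2 and 61.2 CPM in MCC, and 83.1 and 81.2 CPM in iMac. Uty, a demethylase gene on the Y chromosome, was at 14.6 and 14.9 CPM in MEF, 23.0 and 23.1 CPM in MCC, and 44.3 and 36.4 CPM in iMac.

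Genes expressed in MEF and nearly absent in iMac were higher in MCC library 1 than in MCC library 2. The 690 genes taken had 20 CPM or more in MEF and under 1% of that in iMac, and were not picked by tissue. The median left was 5.9% of the MEF level in MCC library 1, 0.429% in MCC library 2, and 0.116% and 0.114% in iMac. Reads carried over from the MEF libraries would bring every gene at the share of its library mix, and at the mix leaving the fewest 7.68% of the genes (95% interval 5.94 to 9.86) lay below 0.25 of the median share in MCC library 1, against 0% in each of 100 draws of counts at a single share, which argues against carry-over as the source of the whole pattern but not of a part. A single share of cells like the MEF is not decided by the spread of the shares, 1.43 times that between the MEF libraries (95% interval 1.28 to 1.59) and between the bounds set for and against it. Nor do Hox genes decide on fibroblasts with the Hox expression of the MEF. The mean log2 share left per gene, groups 11 to 13 minus groups 3 to 9, was -1.5 (permutation p = 0.0297 over genes). From counts summed over the genes of each set, the shares left were 3.06% and 11.3%. Genes of a Hox cluster are not independent, and the 8 genes of groups 11 to 13 had 28 counts in MCC library 1. The 4 clusters are too few for a permutation p under 0.05. The last 2 explanations cannot be told apart, and the labels give no biological difference between the MCC libraries to test.

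Macrophage genes had low counts in the MEF libraries. Over 33 macrophage and pan-leukocyte genes at 100 CPM or more in iMac, the median level in MEF was 0.064% of the iMac level, with quartiles of 0.0214% and 0.382%. Cells like the iMac at a single share among the MEF would give like shares, and the ratio between the quartiles was 17.9 (95% interval 3.8 to 113), from 0.00745% for Rac2 to 30.5% for Arhgdib. Cross-talk between libraries was tested by the same median for fibroblast and matrix genes in iMac. The ratio of the medians was 0.801 (0.493 to 2.31), within the bounds set beforehand for cross-talk. Cross-talk alone would also give like shares, which was not part of those bounds. The spread of the shares argues against it only as the sole source for all 33 genes. For the genes with the lowest shares it could still be the source, with an upper limit of 0.0187% from Rac2, and expression of some of these genes by MEF was not tested.

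Some genes may have very low counts in all libraries because of the way reads were counted, a hypothesis tested here. Protein-coding genes that share 90% or more of their exonic bases with another gene (74 genes) had a median of 0.0211 CPM, and those sharing under 1% (12050 genes) had 13.5 CPM, a ratio of 640. Genes sharing 90% or more with the other strand alone were 86 times lower, but number 10. Genes sharing 50% or more were 4.34 times lower where the share was with the other strand (126 genes, 3.11 CPM) and 75.8 times lower where it was with the same strand (222 genes, 0.178 CPM). Reads left uncounted over shared bases would give such a gap. Whether these genes also differ in their own expression was not tested, so the values do not settle the cause. Why the strands differ was not tested either.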
